A study of Mus musculus with 15 samples.

How the data were processed

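RNA sequencing was applied to striatum, the input nucleus of the basal ganglia, of C57Bl/6J mouse pups at postnatal day 14. The dams had been exposed during pregnancy to aerosols, and the 15 libraries fall into 4 groups: 4 control libraries, 3 from paraquat exposure, 4 from exposure to titanium dioxide (TiO2) nanoparticles and 4 from exposure to the mixture of both. Paraquat is a herbicide that cycles redox, and TiO2 nanoparticles are a common particulate additive. Groups and library numbers were taken from the labels. Per the labels' protocols, RNA was isolated with a NucleoSpin RNA II kit, libraries were made with the Lexogen SENSE total RNA kit and sequencing was done on an Illumina NextSeq500. The labels give no litter, dam, sex, batch or date, and do not say whether the libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical.

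The authors deposited 1 table of 15569 genes by 15 libraries whose values are whole read counts per gene divided by a size factor for each library, a normalised signal that is never negative. This was read from the values: each library's values are whole multiples of a step, the worth of 1 read, which lies between 0.6585 and 1.085. With that step, 100% of values came out whole within 0.001, and the largest distance from a whole number was 7.1e-05. In 4 libraries (paraquat 1, TiO2 3 and 4, mixture 1) the step lies so near 1 (0.9902 to 1.004) that recovery of whole reads is claimed for the other 11 only, while the count tests use all 15. The submitters' processing notes name Bowtie2 2.3.2.2, DESeq2 2.1.8.3 and the mm10 genome. The read counter, the gene annotation, the use of strand and the filter that left 15569 genes are not given in the sources used here. Where strand was not used, reads of a gene and of an overlapping gene on the other strand cannot be told apart. All 15569 gene symbols matched GENCODE M21 on GRCm38, the same assembly as mm10, and coordinates, biotypes and transcript GC content come from that annotation.

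The depth recovered from the steps was 8690925 to 14207513 reads in those 11 libraries, paraquat library 3 being the deepest, and the same division gives 8911693 to 9655747 in the other 4. Each library has 0 to 4 genes at 0, and a floor of 3 reads corresponds to 1.98 to 3.25 units of signal, while the lowest mean over the libraries of any gene is 5.53. Reads without molecular identifiers are not independent molecules, so depth describes counting error only. Each library was counted as its own sample, as the labels list them. Pairs of libraries of a group differed beyond counting noise, with a chi-square per degree of freedom of 3.02 to 25.1, so none is a copy of another, while repeat preparations of the same RNA are not excluded by it.

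The plan fixed before the data were examined assumed raw counts and named edgeR. Because the table holds normalised signal, the main test was limma 3.58.1 in R 4.3.3 on log2(value + 1), with the trend and robust options of its empirical Bayes step. All 15 libraries entered a single fit with a mean for each group. The filterByExpr function of edgeR 4.0.16 kept 15556 genes and dropped 13. Calls were made at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Fold changes are on the log2(value + 1) scale, which understates the change of low genes, and are given with the standard error of the fit. The comparisons were each exposure against control, the exposures against each other, and the interaction, which is the mixture minus paraquat minus TiO2 plus control on the log2 scale. The edgeR quasi-likelihood test on the recovered reads, as written in the plan, became an added alternative and called 1813 genes for paraquat, 996 for TiO2 and 166 for the mixture.

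Genes were named by a rule fixed beforehand. For each exposure against control it took, among called genes with a mean of at least 1 CPM, the 8 largest rises, the 8 largest falls and up to 12 called members of fixed lists by smallest p. For the other comparisons it took the 5 called genes with the smallest p in each direction or, with none called, the 3 smallest p. A set of genes of the dopamine system, glia and oxidative defence was named in any case. Of the genes so chosen, 2 are not reported here. The text also names members of called lists, and genes outside the rule are said to have been chosen after their values were seen.

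Of 39 gene lists of cell types, tissues and pathways fixed in the same plan, 37 had at least 5 tested members. They were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether a set moves on balance one way, were the alternatives. A list score of a library is the mean over members of the log2 difference from the control mean. Library measures were compared by exact two-sided permutation tests. The comparisons against control share 4 control libraries, so overlaps are given beside the value simulated for unchanged groups against those controls, the overlap of independent lists, and the value with the controls split.

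The alternatives were edgeR with TMM or RLE scaling, DESeq2 1.42.0, voom with sample weights, other filters, only the groups compared, each library left out, the replicate number as a block, a score of sex-linked genes as a covariate and 1 surrogate variable (sva 3.50.0). The surrogate variable was −0.296 to −0.254 in the libraries high in Xist and 0.233 to 0.25 in those with Y-linked signal. It thus follows the sex-linked score and is not a separate check. DESeq2 gave no adjusted p to 605 to 9953 genes of a comparison, so its counts were adjusted over fewer genes than those of limma. Added after seeing the data were a pseudocount of 8, TMM scaling in limma and removal of a smooth trend with transcript GC content (loess, span 0.3) from each library. The labels do not say what a shared number means. Deviations from the group means correlated above 0.1 in all 3 same-number pairs of paraquat and mixture libraries (0.114, 0.133 and 0.271). In no other 2 groups did every pair do so, and these libraries were treated as pairs. Each of these pairs also matched in sex-linked signal (Xist or Y-linked genes), and in no other 2 groups did every pair match. Over all groups, same-number pairs that did not match in this signal ran from −0.186 to 0.0265. All 8 same-number pairs above 0.1 matched in it, while the matched pair paraquat 3 and TiO2 3 lay at −0.0984. A shared number without this match thus came with no such correlation. The correlations therefore give no ground of their own for a pairing by number. Paraquat 2 correlated more with mixture 4 (0.337), which it also matched in sex-linked signal. For the mixture against paraquat the block was also run with the GC correction and in a fit of these 2 groups alone, both added after seeing the data. The fit of the 2 groups gives no weight to mixture 4, which has no partner.

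The steps were tested on simulated data with 100 genes changed 1.5-fold and 100 changed 2-fold among 15556. In a simulated paraquat comparison limma recovered 56% of the former and 89% of the latter and called 4 unchanged genes. For TiO2 it recovered 61% and 83% with 6 unchanged genes called, and for the mixture 60% and 90% with 7. For the interaction it recovered 36% and 67% with 4. These simulations held no GC trend. With a GC trend as steep as in these libraries added to the paraquat comparison, limma recovered 49% and 82% and called 39 unchanged genes. After the GC correction it recovered 54% and 84% with 7. In a simulated paraquat comparison with raised myelin genes, camera called the myelin list and 1 other, while camera with an estimated correlation and fry called it alone. Genes were drawn independently there, so this run cannot judge the preset correlation between genes.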

Results

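The libraries cover the striatum of 14-day-old mouse pups after prenatal exposure to control aerosol, paraquat, TiO2 nanoparticles or their mixture. The groups had 4, 3, 4 and 4 libraries. Means below are normalised read counts ± SD over the libraries of a group, and log2 fold changes carry their standard error. The RNA Xist of the inactive X chromosome was at 10600 to 24100 in control 1 and 3, paraquat 2, TiO2 1 and 2, and mixture 2 and 4, while Y-linked genes summed to 784 to 1100 in the other libraries. Mitochondrial transcripts held 21% ± 0.92 of the signal in control, 17.8% ± 0.91 in paraquat, 18.9% ± 1.9 in TiO2 and 19.9% ± 0.97 in the mixture. The exact permutation p against control was 0.0286 for paraquat (n = 3 and 4), 0.0571 for TiO2 and 0.171 for the mixture, with adjusted values of 0.129, 0.129 and 0.205 over 12 such tests. The correlation of a library's deviation with transcript GC content across genes averaged −0.255 in control, 0.247 in paraquat, 0.156 in TiO2 and −0.127 in the mixture (exact permutation p = 0.0857, 0.0857 and 0.543).

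The first comparison asks what paraquat inhaled by the dam changed in the pup striatum. Cyp26b1, the retinoic acid hydroxylase, rose from 10.6 ± 4.05 in control to 62.4 ± 23.3 (log2 fold change 2.45 ± 0.35, adjusted p = 0.000341). The voltage-gated potassium channel gene Kcna3 rose by 2.1 ± 0.29 on the log2 scale, Klhl11 by 1.93 ± 0.20, Xkr4 by 1.64 ± 0.16 and Nkain3 by 1.63 ± 0.17. Other large rises were in Slc17a6, the vesicular glutamate transporter 2 gene, from 13.0 ± 8.43 to 55.3 ± 11.8, the metabotropic glutamate receptor gene Grm2 from 12.1 ± 4.51 to 42.0 ± 25.1, and neuritin (Nrn1) from 28.0 ± 7.96 to 119 ± 107. Among the largest falls, Spata1 went from 33.7 ± 3.2 to 16.9 ± 2.77 (log2 −0.96 ± 0.21, adjusted p = 0.00537) and the noncoding host RNA Snhg6 from 125 ± 3.53 to 68.1 ± 10.4. Others were Trim34a (−1.26), Nanos2 (−1.12), Calhm6 (−1.12), Cytip (−0.95) and Mir17hg (−0.92), at control means of 12.8 to 28.

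In GRCm38, Cyp26b1 lies on chromosome 6 at 84571414 to 84593908, Kcna3 on chromosome 3 at 107036169 to 107038070, Klhl11 on chromosome 11 at 100462614 to 100472741, Xkr4 on chromosome 1 at 3205901 to 3671498 and Nkain3 on chromosome 4 at 20118874 to 20778866. All are annotated as protein coding. Control library 1 stood apart for Cyp26b1 (16.6), Kcna3 (30.0) and Klhl11 (78.7). In other groups, TiO2 library 3 stood apart for Snhg6 (75.3) and mixture library 3 for Rarb (3300).

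In total 1617 of 15556 genes were called by limma, 986 higher and 631 lower, of which 71 rose and 11 fell by more than 2-fold. The split by direction was 1163 and 1014 with voom, 996 and 758 without control 2, and 571 and 165 without paraquat 1. Median transcript GC content was 55.2% for genes called higher and 44.3% for genes called lower, against 49.2% for all genes, and 864 of the calls were kept when a GC trend was removed from each library. The call count was 838 without control 1, 1030 without control 4, 736 without paraquat 1 and 665 without paraquat 3. The call of Slc17a6 ended without control 3, paraquat 1 or paraquat 3 (adjusted p up to 0.0999), and that of Nrn1 without any library except paraquat 1 (0.114). Among the falls, Trim34a was lost without control 4, paraquat 2 or 3 (0.057), Nanos2 without any of the 7 libraries (0.187) and Calhm6 without control 4 or paraquat 3 (0.0845). Cytip was lost without control 4 or paraquat 1 (0.08) and Mir17hg without control 3 or paraquat 3 (0.09) or with the GC correction (0.0512; range over the alternatives from 0.0124). A fit of only the groups compared ended the calls of Slc17a6, Nrn1 and Nanos2, and other alternatives those of Nrn1 and Nanos2, with adjusted p over the alternatives of 0.00133 to 0.0683, 0.00237 to 0.132 and 0.0395 to 0.0756.

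Oligodendrocyte genes stood out among the gene lists after paraquat. Of 18 tested genes of oligodendrocytes and myelin 14 rose and 4 did not pass, and 18 were higher adjusted over the list alone (camera adjusted p = 1.44e-11, adjusted p = 0.561 with an estimated correlation). Myelin basic protein (Mbp) went from 20300 ± 4020 to 39100 ± 1290 (log2 0.97 ± 0.22), and Myrf, the transcription factor of myelination, from 285 ± 33.7 to 530 ± 96.2. Fa2h, which hydroxylates the fatty acids of myelin lipids, rose by 1.25 ± 0.25 on the log2 scale. Of 12 genes of oligodendrocyte precursors 5 rose, among them Sox10 (0.82 ± 0.14) and Olig1 (0.52 ± 0.11), and 7 adjusted over the list alone (camera adjusted p = 0.00153, adjusted p = 0.561 with an estimated correlation). Of 15 astrocyte genes the transcription factor gene Sox9 (0.64 ± 0.11) and the filament gene Gfap (0.52 ± 0.13) rose, and 4 adjusted over the list alone (camera adjusted p = 0.0164, adjusted p = 0.722 with an estimated correlation).

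Some genes of the presynaptic terminal also rose. Of 18 genes of synaptic vesicles and release 8 rose and none fell, and 11 adjusted over the list alone (camera adjusted p = 9.76e-06, adjusted p = 0.198 with an estimated correlation). Rab3a, the vesicle GTPase, went from 2000 ± 190 to 3050 ± 382 (log2 0.60 ± 0.09, adjusted p = 0.000233), the vesicle protein gene Sv2a rose by 0.31 ± 0.07 and piccolo (Pclo), a scaffold of the release site, by 0.32 ± 0.08. Among 34 genes of axon guidance 10 rose, led by Unc5d (0.96 ± 0.14), Ephb2 (0.83 ± 0.16) and Sema4d (0.60 ± 0.11), and 2 fell. On that list 13 were higher and 3 lower adjusted over the list alone (camera adjusted p = 0.00384, adjusted p = 0.237 with an estimated correlation). Of 13 genes of cortical glutamatergic neurons 3 rose, Rasgrf2 (0.61 ± 0.13), Cux2 (0.54 ± 0.13) and Nrn1, and 4 adjusted over the list alone (camera adjusted p = 0.00606, adjusted p = 0.722 with an estimated correlation). The score of this list was 1.584 in paraquat library 2, 0.409 in library 3 and 0.232 in library 1, against −0.643 to 0.278 in control. Of 19 immediate early genes Fos (0.93 ± 0.24) and Btg2 (0.72 ± 0.18) rose, and 4 adjusted over the list alone (camera adjusted p = 0.00606, adjusted p = 0.722 with an estimated correlation).

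Some general and direct-pathway markers of striatal projection neurons were lower after paraquat. The indirect-pathway list was not called, and the difference between the types was not tested. Paraquat library 2, with the highest cortical score (1.584), had the lowest general (−0.208) and direct-pathway (−0.247) scores. The other paraquat libraries had −0.077 and −0.118, and −0.11 and −0.134, also below every control. Cortical tissue in library 2 is not excluded. Of 18 general markers of the medium spiny neurons, the main neurons of the striatum, Rarb (−0.49 ± 0.08, from 4230 ± 232 to 3010 ± 162), Arpp21 (−0.27 ± 0.07) and 2 others fell, and 7 adjusted over the list alone (camera adjusted p = 0.00513, adjusted p = 0.561 with an estimated correlation). Of 10 genes of the direct-pathway type Tac1 (−0.45 ± 0.10), Isl1 (−0.50 ± 0.12) and 1 other fell, and adjusted over the list alone 4 were lower and 1 higher (camera adjusted p = 0.0254, adjusted p = 0.561 with an estimated correlation). Of 9 genes of the indirect-pathway type 1 rose and 1 fell, the same numbers adjusted over the list alone, at a median of 0.061 (camera adjusted p = 0.624) and of −0.079 after the GC correction. Of 80 cytosolic ribosomal protein genes 10 fell, among them Rpl5 (−0.65 ± 0.12) and Rpl4 (−0.35 ± 0.08), and 1 rose. On that list 11 were lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00128, adjusted p = 0.561 with an estimated correlation). Of 74 nuclear-encoded respiratory chain and ATP synthase genes 7 fell, such as the complex I genes Ndufs4 (−0.50 ± 0.11) and Ndufb5 (−0.39 ± 0.09), and 2 rose, with Atp5d going from 717 ± 63.7 to 1270 ± 226. On that list 8 were lower and 2 higher adjusted over the list alone (camera adjusted p = 0.00606, adjusted p = 0.742 with an estimated correlation). Of 7 mitochondrially encoded mRNAs 4 fell, mt-Nd1 (−0.41 ± 0.11) with the smallest p, and mt-Nd6 rose by 0.89 ± 0.18. On that list 6 were lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0405, adjusted p = 0.722 with an estimated correlation). None of 17 interferon response genes was called singly or adjusted over the list alone, and their median log2 fold change was −0.558 (camera adjusted p = 0.00448, adjusted p = 0.722 with an estimated correlation). Scores of this list were −0.579 and −0.783 in control 1 and 3, within the paraquat range of −1.022 to −0.307. Control 2 and 4 had 0.24 and 1.122.

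Of the 13 camera calls for paraquat 6 held without any 1 library (myelin, oligodendrocyte precursor, presynaptic, axon guidance, immediate early and ribosomal protein genes), and 7 depended on single libraries. The astrocyte list was lost without control 3 or paraquat 3 (adjusted p up to 0.285), the cortical list without paraquat 2 (0.216) and the general medium spiny neuron list without paraquat 2 (0.0772). The direct-pathway list was lost without control 3 or paraquat 2 (0.166), the nuclear respiratory list without control 2 (0.317) and the interferon list without control 4 or paraquat 2 (0.118). The mitochondrial list was lost without control 1, 2 or 4 or paraquat 1 or 2 (0.192). Among genes, Mbp lost its call without paraquat 1 or 3 (0.0745), Rasgrf2, Fos and Btg2 without paraquat 3 (0.0585, 0.0945 and 0.0513), Arpp21 without control 3 or paraquat 1 (0.0757) and mt-Nd1 without paraquat 1 (0.112). The GC correction ended the calls of the immediate early list (0.0877), the mitochondrial list (0.454) and mt-Nd1 (0.222), and a fit of only the groups compared that of Arpp21 (0.0502). Over the alternatives adjusted p was 0.00148 to 0.222 for mt-Nd1 and 0.000597 to 0.0502 for Arpp21.

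The second comparison asks the same of TiO2 nanoparticles. Xkr4 rose from 77.3 ± 17.3 to 326 ± 22.4 (log2 2.09 ± 0.15, adjusted p = 3.5e-08), the mu opioid receptor gene Oprm1 from 24.6 ± 7.93 to 99 ± 7.21 (2.02 ± 0.22) and the sodium-proton exchanger gene Slc9a7 from 42.2 ± 9.15 to 143 ± 18.5 (1.76 ± 0.16). Kcna3 rose by 2.33 ± 0.27, Klhl11 by 2.04 ± 0.19, Cyp26b1 by 2.00 ± 0.32, Nkain3 by 1.95 ± 0.16 and the corepressor gene Lcor by 1.79 ± 0.18. Oprm1 lies on chromosome 10 at 6758506 to 7038198, Slc9a7 on chromosome X at 20105754 to 20291807 and Lcor on chromosome 19 at 41482637 to 41562261. The falls were smaller than these rises: Bbox1 (−1.49 ± 0.38), Cybb (−1.47 ± 0.42), which encodes the catalytic subunit of the phagocyte NADPH oxidase, Trim34a (−1.07 ± 0.30), Cenpu (−1.04 ± 0.29), Col4a4 (−0.98 ± 0.28), Egfem1 (−0.84 ± 0.23), Ppil6 (−0.78 ± 0.23) and Mir17hg (−0.76 ± 0.23) had control means of 10.8 to 36.7.

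In total 996 genes were called by limma, 669 higher and 327 lower, with 41 rises and 18 falls over 2-fold. The excess of rises depended on the fit, with 897 higher and 690 lower by voom, 764 and 633 without control 2, 715 and 550 without TiO2 4, and 365 and 102 without TiO2 3. Median GC content was 54.3% for genes called higher and 43.5% for those called lower, and 617 calls were kept after the GC correction. Counts were 502 without control 1, 582 without control 4, 536 without TiO2 2 and 467 without TiO2 3. Every named fall was lost without several libraries in turn. Bbox1 was lost without control 1, 3 or 4 or TiO2 3 (adjusted p up to 0.0864), Cybb without any library except TiO2 4 (0.123) and Trim34a without control 2, 3 or 4 or TiO2 3 or 4 (0.122). Cenpu (0.0986), Ppil6 (0.138) and Mir17hg (0.113) were lost without any library except control 2 and TiO2 4, Col4a4 without any except control 2 (0.116) and Egfem1 without control 1 or 3 or TiO2 3 or 4 (0.0852). The GC correction ended the calls of Cybb (0.0582), Trim34a (0.0542), Ppil6 (0.0574) and Mir17hg (0.105), where the lowest adjusted p over the alternatives was 0.0146, 0.0245, 0.0155 and 0.0132. Control library 2 stood apart for Ppil6 at 27.9, where the others had 39.3 to 40.4.

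Some immediate early genes, which neurons induce on activity, rose after TiO2. Of 19 genes 5 rose and 9 were higher adjusted over the list alone (camera adjusted p = 0.000448, adjusted p = 0.537 with an estimated correlation). TiO2 library 3 had the highest score of this list (0.705) and of the cortical list (0.794) in its group. Cortical scores of TiO2 1, 2 and 4 were −0.209, 0.431 and 0.594, against at most 0.278 in control. The cortical list was not called, and the immediate early list kept its camera call without any 1 library. Egr1 went from 2970 ± 490 to 5430 ± 562 (0.88 ± 0.16), and Fosl2 rose by 0.49 ± 0.12. Mixture library 4 stood apart for Egr1 at 3320, where the others of its group had 4770 to 4970. Of 12 oligodendrocyte precursor genes C1ql1 (0.67 ± 0.15), a secreted protein gene, and 2 others rose, and 8 adjusted over the list alone (camera adjusted p = 0.000805, adjusted p = 0.537 with an estimated correlation). Of 18 presynaptic genes Rab3a (0.59 ± 0.08), Pclo (0.31 ± 0.07) and 1 other rose, and 6 adjusted over the list alone (camera adjusted p = 0.00114, adjusted p = 0.537 with an estimated correlation). Of 18 myelin genes Myrf alone was called (0.61 ± 0.15), also adjusted over the list alone (camera adjusted p = 0.00127, adjusted p = 0.832 with an estimated correlation). Of 15 astrocyte genes Sox9 (0.41 ± 0.10) and 3 others rose, 4 also adjusted over the list alone (camera adjusted p = 0.0139, adjusted p = 0.832 with an estimated correlation).

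Of 34 axon guidance genes Unc5d rose (0.44 ± 0.13), and 5 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0413, adjusted p = 0.537 with an estimated correlation). Of 80 ribosomal protein genes Rpl5 (−0.44 ± 0.11) and 2 others fell and 2 rose, in the same numbers adjusted over the list alone (camera adjusted p = 0.0413, adjusted p = 0.832 with an estimated correlation). None of 17 interferon genes was called in either way, at a median of −0.453 (camera adjusted p = 0.0152, adjusted p = 0.832 with an estimated correlation). The scores of control 1 and 3 (−0.579 and −0.783) lay within the TiO2 range of −0.852 to −0.21, and those of control 2 and 4 above it. Outside the called lists, Gabrb2, a GABA-A receptor subunit gene, rose from 418 ± 88.5 to 903 ± 52.4, Atp5d to 1440 ± 192, the clock genes Nr1d1 (0.72 ± 0.11) and Per1 (0.61 ± 0.11), the cochaperone gene Bag3 (1.09 ± 0.21), Sdhc (0.41 ± 0.08), Grm3 (0.39 ± 0.08) and mt-Nd6 (0.76 ± 0.16) rose, and Rarb fell (−0.38 ± 0.07). Camera calls ended for myelin without control 3 (adjusted p = 0.099), for astrocytes without control 3 (0.0507) and for interferon genes without control 2 or 4 or TiO2 1 or 4 (up to 0.49). They ended without control 2 or TiO2 3 or 4 for axon guidance (up to 0.169) and ribosomal proteins (up to 0.306). Gene calls ended for Myrf without control 1 or TiO2 2 or 3 (up to 0.0683), Sox9 without control 1 (0.051), Fosl2 and Rpl5 without control 1 or TiO2 3 (up to 0.0778 and 0.0629) and Unc5d without any library except control 3 and TiO2 1 (up to 0.141). Unc5d was also lost with only the groups compared or voom (0.0103 to 0.0872 over the alternatives).

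The third comparison asks what the mixture changed. Xkr4 rose to 231 ± 37.1 (log2 1.58 ± 0.15, adjusted p = 7.43e-06), Klhl11 to 118 ± 11.1 (1.44 ± 0.19) and Slc9a7 to 105 ± 21.8 (1.30 ± 0.16), and Cyp26b1 (1.80 ± 0.32), Kcna3 (1.61 ± 0.27), Oprm1 (1.37 ± 0.22) and Lcor (1.29 ± 0.18) rose as they had with the single exposures. The inward rectifier potassium channel gene Kcnj6 (chromosome 16, 94748636 to 94997701) rose from 12.3 ± 3.85 to 37.9 ± 9.79. Mitochondrial mt-Nd6 rose from 63.6 ± 18.7 to 151 ± 21.7 (1.27 ± 0.16, adjusted p = 0.000109). Among the falls were Psmc3ip (−0.69 ± 0.16), Dkc1 (−0.54 ± 0.12), Spcs1 (−0.33 ± 0.08), Vcam1 (−0.32 ± 0.08), Smpdl3a (−0.32 ± 0.08), Pbx3 (−0.31 ± 0.07) and Tnfrsf19 (−0.29 ± 0.07). TiO2 library 3 stood apart for Spcs1 at 718.

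Limma called 185 genes, 174 higher and 11 lower, with 26 rises and 1 fall over 2-fold, the fall in a predicted noncoding gene outside the naming rule. The number of falls depended on the fit, with 45 by voom, 34 after the GC correction, 32 by DESeq2 and 0 without mixture 3. The count was 96 without control 1, 103 without control 2 and 86 without control 4, and 80, 84 and 52 without mixture 1, 2 and 3. Every named fall was lost without several libraries in turn. Dkc1 was lost without control 1 or 4 or mixture 2 or 3 (adjusted p up to 0.0798), Psmc3ip without any library except control 1 (0.118), Spcs1 without any except mixture 1 (0.189) and Pbx3 without any except control 2 (0.125). Vcam1 (0.135), Smpdl3a (0.154) and Tnfrsf19 (0.129) were lost without any of the 8. The GC correction ended the call of Vcam1 (0.079; 0.00513 to 0.079 over the alternatives), and voom that of Cyp26b1 (5.93e-05 to 0.0541).

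Presynaptic, cortical and immediate early genes had the smallest p among the lists in the mixture. Of 18 presynaptic genes Rab3a (0.38 ± 0.08), Pclo (0.33 ± 0.07) and 1 other rose, and 9 adjusted over the list alone (camera adjusted p = 4.93e-08, adjusted p = 0.0569 with an estimated correlation). Of 19 immediate early genes Fos (1.11 ± 0.22), Nr4a3 (0.90 ± 0.18) and Fosl2 (0.63 ± 0.12) rose, and 9 adjusted over the list alone (camera adjusted p = 3.35e-07, adjusted p = 0.349 with an estimated correlation). None of 13 genes of cortical glutamatergic neurons passed over all genes, while 10 were higher adjusted over the list alone, at a median log2 fold change of 1.34 (camera adjusted p = 2.97e-07, adjusted p = 0.368 with an estimated correlation). The score of that list was 0.776 to 1.451 in the 4 mixture libraries, all above the highest control score of 0.278. Cortical tissue in these samples therefore cannot be told apart from an effect of the mixture. Of 34 axon guidance genes Unc5d (0.68 ± 0.13) and 1 other rose, and 5 were higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0129, adjusted p = 0.349 with an estimated correlation). No myelin gene was called singly or adjusted over the list alone among 18 that had a median of 0.266 (camera adjusted p = 0.000814, adjusted p = 0.765 with an estimated correlation).

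Interferon genes, 17 tested and none called in either way, had a median of −0.63 (camera adjusted p = 8.85e-05, adjusted p = 0.59 with an estimated correlation). The 18 medium spiny neuron markers had none called, 1 lower adjusted over the list alone and a median of −0.088 (camera adjusted p = 0.00712, adjusted p = 0.512 with an estimated correlation). The 80 ribosomal protein genes had none called in either way (median −0.086, camera adjusted p = 0.0299, adjusted p = 0.657 with an estimated correlation), and 13 glucocorticoid-induced genes had none called and 1 higher adjusted over the list alone (median 0.199, camera adjusted p = 0.042, adjusted p = 0.59 with an estimated correlation). Outside these lists Gabrb2 (0.84 ± 0.12), Col1a1 (0.80 ± 0.17), Shank1 (0.65 ± 0.14), Atp5d (0.50 ± 0.11) and Grik3 (0.35 ± 0.08) rose. Control library 2 stood apart for Col1a1 at 117.

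Camera calls for the mixture ended without control 2 for axon guidance (adjusted p = 0.0641), control 3 for myelin (0.174), control 4 for interferon genes (0.0606) and mixture 4 for medium spiny neurons (0.117). Ribosomal proteins were lost without control 2 or mixture 2 or 3 (up to 0.333) and glucocorticoid genes without control 3 or 4 or mixture 2 or 3 (up to 0.261). Gene calls ended for Fos without mixture 1 or 2 (up to 0.0546), Rab3a without control 1 or 2 or mixture 1 or 3 (0.0927) and Pclo without control 2 or mixture 2, 3 or 4 (0.0795). They ended for Nr4a3 without control 2 or 4 or mixture 1, 3 or 4 (0.0735), Col1a1 without control 1, 3 or 4 or mixture 2 or 3 (0.0907) and Atp5d without control 1 or 4 or mixture 1, 2 or 3 (0.106). Grik3 was lost without control 1 or 4 or mixture 1, 3 or 4 (0.0809) and Shank1 without control 1, 2 or 4 or mixture 1, 3 or 4 (0.0989) or with the GC correction (0.0699; 0.00141 to 0.0699 over the alternatives).

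**Figure D1:**
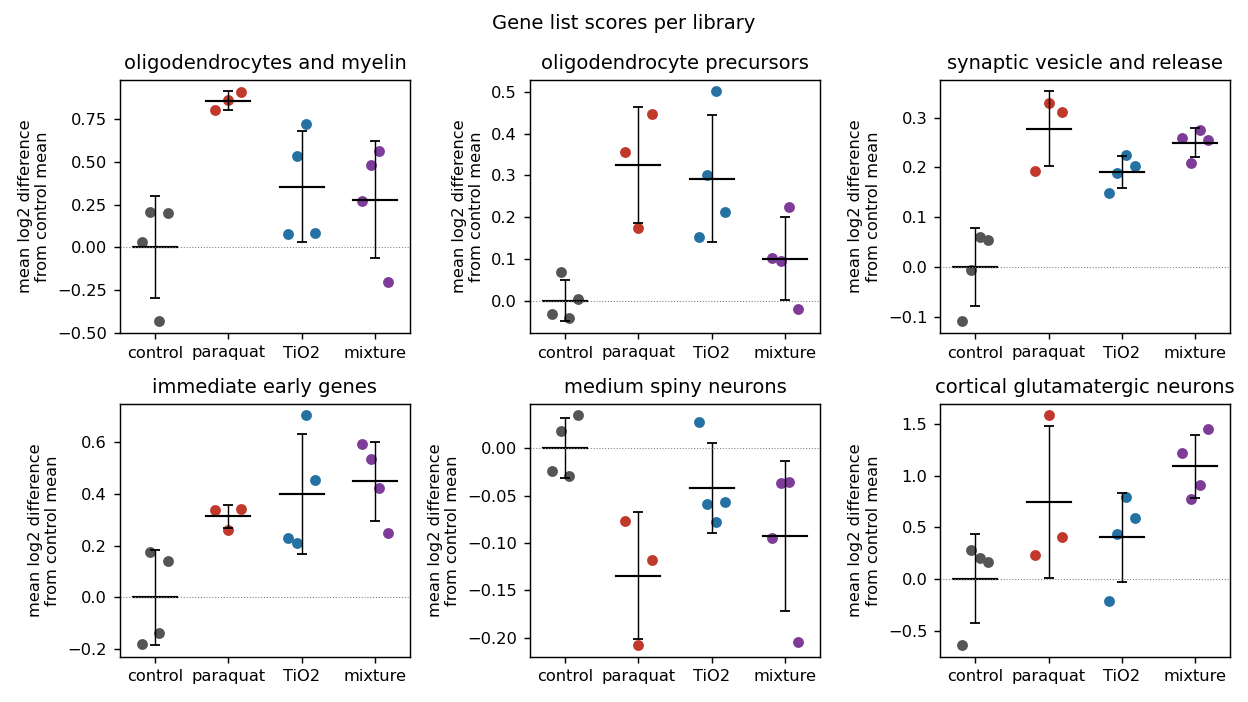
Gene list scores of 6 lists in the 15 libraries; the vertical axis is the mean log2 difference from the control mean over list members, points are libraries, horizontal lines are group means and bars are SD. The 3 paraquat libraries had myelin scores of 0.802, 0.86 and 0.912 against a highest control score of 0.204, and the 4 mixture libraries had cortical scores of 0.776 to 1.451.

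Genes changed by the 3 exposures overlapped. Called higher in all 3 were 118 genes, among them the ion channel and transporter genes Kcna3, Slc9a7 and Gabrb2, the presynaptic genes Rab3a and Pclo, Xkr4, Oprm1 and mt-Nd6. Called lower in all 3 were 2 genes. The median log2 fold change of the 118 genes was 0.71 in paraquat, 0.67 in TiO2 and 0.52 in the mixture. The rise was smallest in the mixture for 67 of them and largest in the mixture for 12. Of the genes called higher in the mixture 67.8% were also called higher in both single exposures.

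Paraquat and TiO2 shared 616 calls of the same direction, 446 higher and 170 lower, and none of opposite direction, where independent lists would share 42.4 and 13.3. Paraquat and the mixture shared 145 higher and 7 lower (independent 11 and 0.446), and TiO2 and the mixture 125 and 4 (independent 7.48 and 0.231). Simulated unchanged groups against the same controls shared 0 called genes in each of 100 simulations, which sets no level for an overlap of called genes. With the controls split 2 and 2 the same-direction overlaps were 105 to 162, 21 to 63 and 18 to 46. Across genes, which are not independent replicates, fold changes correlated at 0.743, 0.665 and 0.651, where simulated unchanged groups gave 0.465, 0.468 and 0.488 and at most 0.892, 0.852 and 0.875. The observed correlations thus lay within the range of unchanged groups, and with the controls split their medians were 0.415, 0.319 and 0.252. The covariances were 0.0603, 0.046 and 0.0398 against simulated values of 0.0183, 0.0183 and 0.0174.

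**Figure D2:**
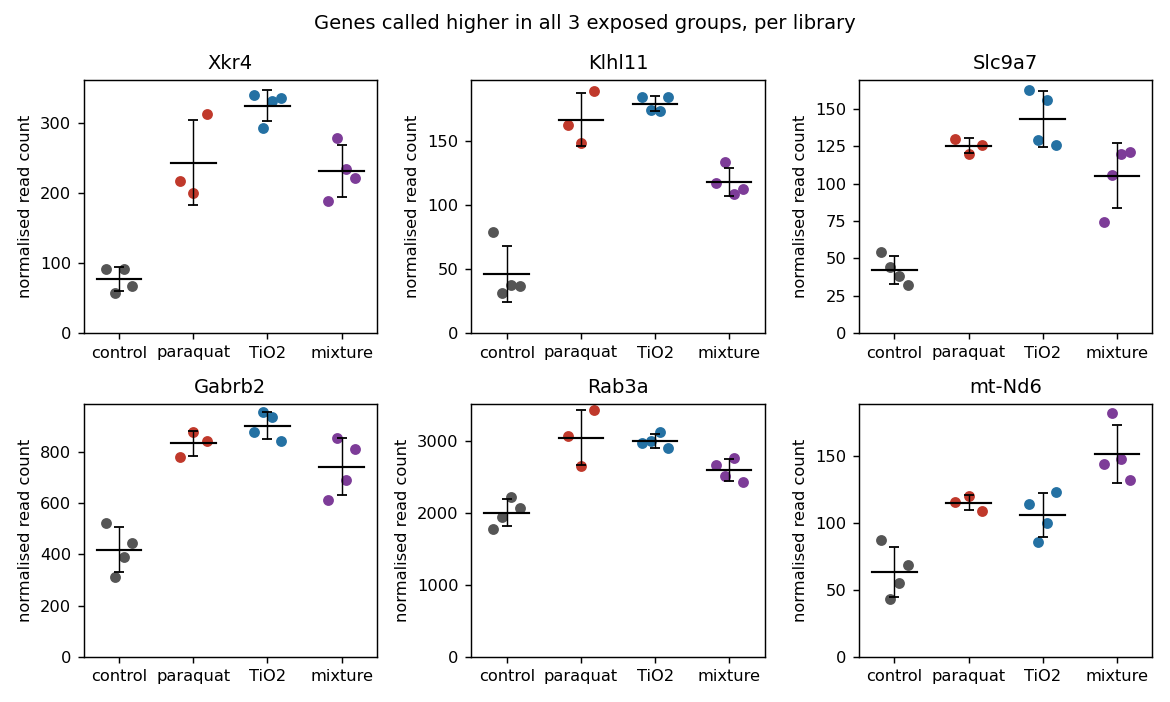
Normalised read counts of 6 genes called higher in all 3 exposed groups; points are libraries, horizontal lines group means and bars SD. Xkr4 averaged 77.3 in control and 231 to 326 in the exposed groups, and mt-Nd6 averaged 63.6 in control and 151 in the mixture.

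The mixture was then set against each single exposure, which asks whether the second agent added a change. Against paraquat the long noncoding RNA gene Dbpht2 alone was called, at 965 ± 117 in the mixture and 649 ± 55.6 in paraquat (log2 0.57 ± 0.09, adjusted p = 0.0158). It lies on chromosome 12 at 74296668 to 74302008. As lists, myelin genes were lower in the mixture than in paraquat (median −0.56, none of 18 called, 8 lower adjusted over the list alone, camera adjusted p = 6.49e-10, adjusted p = 0.934 with an estimated correlation). So were oligodendrocyte precursor genes (median −0.218, none of 12 called, 4 lower adjusted over the list alone, camera adjusted p = 0.00336, adjusted p = 0.934 with an estimated correlation). Mitochondrially encoded mRNAs were higher (median 0.358, none of 7 called, 7 higher adjusted over the list alone, camera adjusted p = 0.000963, adjusted p = 0.934 with an estimated correlation). The call of Dbpht2 ended without paraquat 1 or 3 or mixture 1, 2 or 4 (adjusted p up to 0.251) and after the GC correction (0.0501; 2.58e-06 to 0.0501 over the alternatives), and the precursor list lost its call without paraquat 3 (0.191). With the replicate block the 3 lists kept their camera calls, while adjusted over the list alone 1 myelin gene and 3 precursor genes were lower and no mitochondrial mRNA was higher. Nuclear-encoded respiratory chain genes (median 0.061, none of 74 called, 7 higher adjusted over the list alone) and ribosomal protein genes (median 0.076, none of 80 called, 2 higher adjusted over the list alone) were also called higher in the mixture with the block. Both went to a camera adjusted p of 0.00479, from 0.136 and 0.0728 without the block (adjusted p = 0.996 with an estimated correlation and the block). The block with the GC correction kept both (0.000448 and 0.000483) and called 5 genes, without Dbpht2 (0.0554). A block fit of these 2 groups alone gives no weight to mixture 4, which has no partner, so it compares 3 pairs. That library had the lowest myelin score of its group (−0.203, the others 0.271 to 0.562). In this fit, which leaves far fewer residual degrees of freedom than the fit of all 15 libraries, 107 genes were called. Among them 10 myelin and 3 precursor genes were lower and 2 mitochondrial mRNAs and 2 respiratory genes higher (16, 4, 7 and 8 adjusted over the list alone, with 1 respiratory gene lower). The respiratory list was kept (0.00609) but not the ribosomal one (0.125). With an estimated correlation adjusted p in this fit was 0.863 for the myelin and respiratory lists and 0.957 for the precursor and mitochondrial lists. At an unadjusted p under 0.05 limma counted 2235 genes, and edgeR called 1, voom 67 and DESeq2 138 at the adjusted threshold. DESeq2 gave no adjusted p to 9953 genes here, so its count was adjusted over fewer genes. Without paraquat 2 limma called 3 genes.

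Between the mixture and TiO2 limma called 0 genes, with 1768 at an unadjusted p under 0.05; edgeR called 0, voom 41 and DESeq2 55. Among the genes with the smallest p were Sox18, an endothelial transcription factor gene, at 179 ± 34.9 in the mixture and 285 ± 37.3 in TiO2, and Ccpg1 at 229 ± 9.77 and 152 ± 25, both with adjusted p = 0.141. Cortical neuron genes were higher in the mixture (median 0.838, none of 13 called in either way, camera adjusted p = 0.00229) and oligodendrocyte precursor genes lower (median −0.194, none of 12 called, 2 lower adjusted over the list alone, camera adjusted p = 0.00235). Ependymal genes were higher (median 0.64, none of 10 called, 3 higher adjusted over the list alone, camera adjusted p = 0.0103), as were genes of immature neurons (median 0.367, none of 16 called in either way, camera adjusted p = 0.0334). For all 4 lists adjusted p = 0.934 with an estimated correlation. Without TiO2 4 limma called 14 genes and the ependymal list was lost (adjusted p = 0.276), and the immature neuron list was lost without TiO2 1, TiO2 4, mixture 1 or mixture 4 (up to 0.401).

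Between paraquat and TiO2 limma called 0 genes, with 997 at an unadjusted p under 0.05; edgeR called 0, voom 11 and DESeq2 15. The smallest p belonged to Gpx6 at 285 ± 37.5 and 402 ± 28.1, Osbpl3 at 480 ± 56.3 and 700 ± 51.9, and the neuropeptide gene Cartpt at 50.9 ± 8.41 and 19.8 ± 3.14, all with adjusted p = 0.119. Myelin genes were higher in paraquat than in TiO2 (median 0.473, none of 18 called, 1 higher adjusted over the list alone, camera adjusted p = 9e-12, adjusted p = 0.634 with an estimated correlation). Medium spiny neuron markers were lower (median −0.105, none of 18 called in either way, camera adjusted p = 0.00427, adjusted p = 0.634 with an estimated correlation). Ependymal (0.00649), choroid plexus (0.0275), cortical (0.0352) and presynaptic (0.0352) genes were higher and ribosomal (0.0352) and mitochondrially encoded (0.0488) genes lower by camera, with no member called. Adjusted over the list alone 3 ependymal genes and 1 choroid plexus gene were higher. For these 6 lists adjusted p = 0.634 to 0.798 with an estimated correlation.

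All these lists except myelin depended on single libraries. Medium spiny neurons were lost without paraquat 2 (adjusted p = 0.124), ependyma without paraquat 1 or TiO2 4 (up to 0.343) and choroid plexus without paraquat 3 or TiO2 1 or 3 (up to 0.303). Cortex was lost without paraquat 2 or TiO2 1 or 2 (up to 0.979) and ribosomal proteins without paraquat 3 or TiO2 1 or 2 (up to 0.585). Presynaptic genes (up to 0.209) and mitochondrial mRNAs (up to 0.408) were each lost without 5 of the 7 libraries, held only without paraquat 1 or TiO2 3 in the former and without paraquat 3 or TiO2 3 in the latter. The GC correction ended the calls of presynaptic (0.0745) and mitochondrial (0.0834) genes. Without TiO2 3 limma called 11 genes and without paraquat 2 it called 2.

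The interaction asks whether the mixture departed from the sum of the single effects. Limma called 1832 genes, 842 with a mixture above and 990 with a mixture below the sum. Below it were Klhl11 (−2.53 ± 0.28), Nkain3 (−2.30 ± 0.24), Xkr4 (−2.15 ± 0.22), Slc9a7 (−2.03 ± 0.23) and Usp9x (−1.18 ± 0.13), a deubiquitinase gene at 627 ± 78.7 in control, 1080 ± 66.1 in paraquat, 1220 ± 29.9 in TiO2 and 932 ± 94.7 in the mixture. Above it were Dbpht2 (0.94 ± 0.12), Thoc2 (0.89 ± 0.14), Psmd12 (0.87 ± 0.14) and Rragb (0.76 ± 0.12). Single libraries stood apart for Rragb (control 2 at 918) and Psmd12 (mixture 2 at 508).

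Of 18 myelin genes 8 lay below the sum, 13 adjusted over the list alone (camera adjusted p = 1.25e-07, adjusted p = 0.85 with an estimated correlation), and of 12 oligodendrocyte precursor genes 6, 10 adjusted over the list alone (camera adjusted p = 0.000158, adjusted p = 0.681 with an estimated correlation). Below it were also 2 of 18 presynaptic genes, the same number adjusted over the list alone, and 3 of 15 astrocyte genes, 5 adjusted over the list alone (camera adjusted p = 0.0138 for both, adjusted p = 0.681 and 0.85 with an estimated correlation). Of 34 axon guidance genes 5 lay below and 1 above, 8 and 1 adjusted over the list alone (0.0348, adjusted p = 0.681 with an estimated correlation). Of 80 ribosomal protein genes 7 lay above and 3 below, in the same numbers adjusted over the list alone (0.0138), and of 7 mitochondrially encoded mRNAs 2 lay above, 6 adjusted over the list alone (0.0332), both with adjusted p = 0.85 with an estimated correlation.

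The interaction count was 1203 without control 1, 882 without paraquat 1, 1179 without paraquat 3, 1011 without TiO2 3, 1196 without mixture 2 and 1098 without mixture 4. It was 1139 after the GC correction, which kept 776 of the calls and ended those of the presynaptic (0.0841) and mitochondrial (0.579) lists. Camera calls ended for astrocytes without paraquat 3 (0.0751), presynaptic genes without paraquat 2 (0.0764) and ribosomal proteins without control 2, paraquat 3 or TiO2 4 (up to 0.0863). They ended for mitochondrial mRNAs without control 2, paraquat 1 or 2 or mixture 2 or 3 (up to 0.0764) and for axon guidance without control 2, paraquat 2 or 3, TiO2 4 or mixture 1 or 3 (up to 0.0863).

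**Figure D3:**
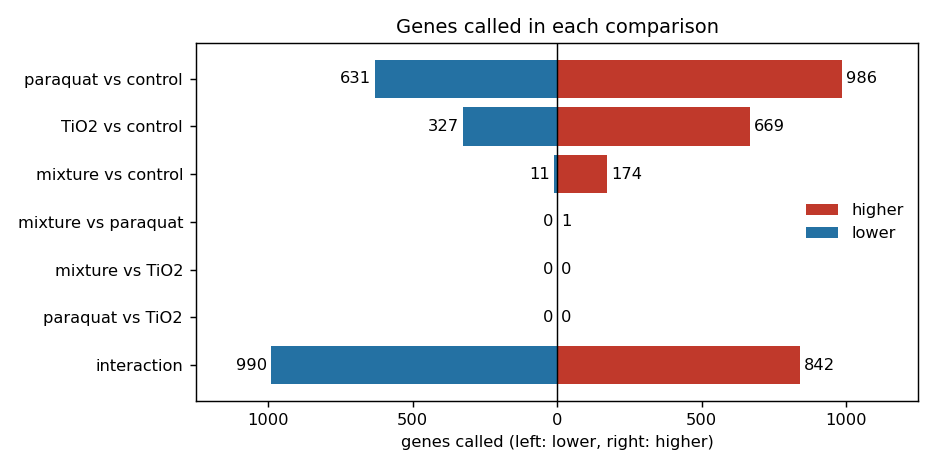
Number of genes called higher (right) and lower (left) in each comparison, out of 15556 tested. The interaction had 842 and 990 calls, while mixture vs TiO2 and paraquat vs TiO2 had 0.

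Genes of the dopamine system were mostly not called. The receptor genes Drd1 and Drd2, tyrosine hydroxylase (Th) and Ppp1r1b, the DARPP-32 gene, passed in none of the exposures, with log2 fold changes of −0.20 to 0.19 for the receptors and −0.29 to 0.08 for the others. The peptide gene Tac1 fell in paraquat (from 3710 ± 375 to 2710 ± 157) and TiO2 (2820 ± 354) and was at 3270 ± 289 in the mixture, which was not called (adjusted p = 0.431). The enkephalin gene Penk fell in paraquat (−0.31 ± 0.10, adjusted p = 0.0486) but not under edgeR (0.0526) or with only the groups compared (0.0197 to 0.0648 over the alternatives), and its call ended without any library except control 3 (up to 0.192). The oxidative defence genes Hmox1 and Nqo1, the microglial gene Aif1 and the choroid plexus gene Ttr were called in none of the exposures. Gfap was called only in paraquat, and its difference between exposures was not called. Single libraries stood apart for Hmox1 (mixture 2 at 79.2), Gfap (control 2 at 395) and Ttr (control 4 at 73.7, the other controls at 1.04 to 12.4).

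Of the 82 genes named by the rule, 25 share exon bases with an annotated gene on the other strand, so their values are uncertain where strand was not used in counting. With a gene on the same strand 4 share exon bases, which leaves their values uncertain even where strand was used. Among these 4 is Ccpg1, with 42.9% shared with Gm44503. The share of exon bases with the other strand was 49% for Nanos2, 34.1% for Rarb (with Top2b), 28.9% for Ccpg1 (with Pigb), 26.7% for Cenpu (with Primpol), 24.3% for Rpl5 (with Fam69a), 23.5% for Trim34a, 22.3% for Nrn1 (with Fars2) and 21.2% for Psmc3ip (with Mlx). The gene mt-Nd6 shares 14 bases with mt-Nd5, whose mean signal was 143000 against 108 for mt-Nd6, and is the mitochondrial mRNA read from the other strand. Ribosomal protein genes, Trim34a and Gstm1 have close paralogs or pseudogenes, and how reads shared with them were counted is not given.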

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

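The tests of opposite-strand overlap and of other splits of the samples were written before their results were seen, and the tests of GC content, control handling, a control shift, neuron share and cortical tissue were chosen after. Single libraries lay far from the others of their group in 17 of 294 groups of 4 tested, with a gap to the nearest library above 0.829 of the range. Chance gives this in about 1 in 20 groups.

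Control 1 had 16.6 for Cyp26b1 (others 7.86 to 9.29), 30 for Kcna3 (8.85 to 10.6) and 78.7 for Klhl11 (31 to 37.2). Control 2 had 27.9 for Ppil6 (39.3 to 40.4), 117 for Col1a1 (73.4 to 76.7), 918 for Rragb (943 to 947) and 395 for Gfap (292 to 304). Control 4 had 73.7 for Ttr (1.04 to 12.4). TiO2 3 had 75.3 for Snhg6 (103 to 108) and 718 for Spcs1 (850 to 862). Mixture 2 had 508 for Psmd12 (434 to 437) and 79.2 for Hmox1 (96.7 to 99), mixture 3 had 3300 for Rarb (3540 to 3570) and mixture 4 had 3320 for Egr1 (4770 to 4970). Among the list scores, TiO2 1 had 0.091 for astrocytes (0.198 to 0.217) and control 1 had −0.643 for cortical neurons (0.167 to 0.278).

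Measured against the shared controls, whose shift alone could give such calls too, the mixture differed from the sum of the single effects (interaction) for 1832 genes. Among them were Dbpht2 (0.94), Thoc2 (0.89), Rragb (0.76), Psmd12 (0.87), Nkain3 (−2.30), Usp9x (−1.18), Xkr4 (−2.15), Slc9a7 (−2.03) and Klhl11 (−2.53).

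The first pattern weighed is the rise of 118 genes in all 3 exposures. Against a GC trend as its whole cause, 92 of the 118 were still called in all 3 after the GC correction, with median log2 fold changes of 0.67 in paraquat, 0.60 in TiO2 and 0.51 in the mixture. Against reads from the opposite strand, 33.1% of the set shared exon bases with a gene on the other strand, where 29.9% of all genes did (Fisher exact p = 0.48). Handling of the control libraries apart from the exposed ones cannot be told apart from an effect of exposure, since no batch or date is given, and 270 genes had all 11 exposed libraries above all 4 controls, where chance gives 11.4. A shared response of the pups to inhaled exposure in gestation stays open as a hypothesis that was not tested, and libraries of exposed and control pups of known litters prepared in the same batches could decide it.

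The second pattern is the interaction, whose fold changes correlated with those of paraquat at −0.863, of TiO2 at −0.849 and of the mixture at −0.363. It subtracts both single exposures and adds control, so noise alone correlates it negatively with paraquat and TiO2. No value for unchanged groups was computed, so the correlations with paraquat and TiO2 do not measure the pattern. A shift of the control libraries alone moves each comparison against control alike and so returns in the interaction with the opposite sign. The mixture against the mean of the single exposures, a contrast without the controls, had 3 called genes by limma and 2424 at an unadjusted p under 0.05. A control shift and a response that levels off when both agents are given leave the same values, so they cannot be told apart here.

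The third pattern is the rise of myelin genes in paraquat. Against a GC trend, their median log2 fold change was 0.816 after the correction and 0.849 before. Against a lower share of neurons, which raises markers of all other cell types alike, the medians of the microglial and endothelial lists were 0.041 and −0.063 (standard errors of the means 0.05 and 0.048), and −0.068 and 0.017 after the GC correction. Tissue from beside the striatum cannot be told apart: the cortical score was at or below the highest control in 1 of the 3 paraquat libraries (0.232 against 0.278, its myelin score 0.802), the thalamic and hypothalamic scores were 0.358, 0.268 and 0.52 against a highest control of 0.196 (list not called, camera adjusted p = 0.419), and the choroid plexus list had a median of 0.666 with 3 of 6 members higher over the list alone (0.0799, and 0.0489 after the GC correction). Faster maturation of oligodendrocytes after paraquat stays open as a hypothesis that was not tested, and counts of precursor and myelinating cells in striatal sections could decide it.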

How the results depend on the processing

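The use of the planned edgeR test as an alternative in place of the main test, the pseudocount of 8, TMM scaling in limma, the GC correction, the 2 further block fits and the alternatives for the overlaps were chosen after seeing the data, and the other settings before. No call of a named gene reversed its direction, and for the other called genes the direction was not compared between settings. Among lists that were not called the GC correction turned the sign of several medians, among them the paraquat medians of microglia (0.041 to −0.068), endothelial cells (−0.063 to 0.017) and indirect-pathway neurons (0.061 to −0.079) and the TiO2 median of dopamine genes (−0.028 to 0.028). The counts of 1617 (paraquat), 996 (TiO2), 185 (mixture) and 1832 (interaction) stayed within 1.5 times under all settings with all libraries except those given here, and the cause of the differences was not tested. TiO2 had 1587 with voom. The mixture had 300 with DESeq2, 290 with the replicate block and 307 with voom. Mixture against paraquat, 1 by limma, had 138 with DESeq2, 67 with voom, 8 with only the groups compared, 3 with TMM scaling and 2 with the GC correction. Mixture against TiO2, 0 by limma with 1768 at an unadjusted p under 0.05, had 55 with DESeq2, 41 with voom, 6 with the GC correction and 5 with the block. Paraquat against TiO2, 0 by limma with 997 at an unadjusted p under 0.05, had 15, 11 and 3 with DESeq2, voom and the block. The interaction had 1139 with the GC correction.

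Leaving out 1 library gave 665 to 1754 (paraquat), 467 to 1397 (TiO2), 52 to 164 (mixture), 0 to 3 (mixture against paraquat), 0 to 14 (mixture against TiO2), 0 to 11 (paraquat against TiO2) and 882 to 2313 (interaction). The overlap of paraquat and TiO2 (616) was 307 to 815 by leaving out, 1179 at an adjusted p under 0.1 and 123.5 with the controls split. Paraquat and mixture (152) had 49 to 169, 281 and 34, and 244 with DESeq2 and 238 with the block. TiO2 and mixture (129) had 45 to 132, 243 and 31, and 205 with DESeq2, 212 with the block and 203 with voom. Splitting leaves 2 controls to each comparison, so fewer calls are expected from it.

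Camera with an estimated correlation called 0 lists in each of the 7 comparisons. Fry called 6 (paraquat), 4 (TiO2), 1 (mixture), 0, 0 and 0 (between exposures) and 3 (interaction). Camera called 13, 8 and 9 lists against control, 10 to 13, 5 to 10 and 7 to 11 by leaving out. It called 3, 4 and 8 between exposures (2 to 8, 3 to 7 and 3 to 10) and 7 for the interaction (4 to 10). Mixture against paraquat had 7 with the GC correction, 5 with the block, 5 with both and 4 with the block in a fit of the 2 groups. Among named genes, leaving out 1 library ended a call 311 times and added a call 28 times, the GC correction ended 21 calls and added 4, and DESeq2 ended 0 and added 28. Same-number libraries of paraquat and mixture correlated in every pair but also matched in sex-linked signal. Some same-number pairs of other groups matched in it too, such as control 1 and TiO2 1 (0.248) and paraquat 3 and TiO2 3 (−0.0984). Of all 21 same-number pairs 8 correlated above 0.1 (−0.186 to 0.271), and 4 libraries correlated best with their own number. These 8 pairs all matched in sex-linked signal, and the pairs that did not match reached at most 0.0265. Mixture against paraquat had 1 call with the block, 5 with the GC correction as well and 107 in a fit of the 2 groups, and the block changed no other camera call or gene call there than those given with the comparison. With the block the counts were 1482 (paraquat), 1354 (TiO2) and 1768 (interaction). The block ended the camera calls of mitochondrial mRNAs in paraquat (adjusted p = 0.0853), paraquat against TiO2 (0.124) and the interaction (0.0523), of ribosomal proteins in TiO2 (0.0529) and of glucocorticoid genes in the mixture (0.0657). It added those of nuclear respiratory genes in paraquat against TiO2 (0.00413) and the interaction (0.00685), and of axon guidance (0.0391) and immature neuron genes (0.0218) in paraquat against TiO2. It ended the gene calls of Mir17hg in TiO2, Penk in paraquat and Nr4a3 and Cryab in the mixture, and among genes named in the text it added those of Sox18 in mixture against TiO2 (0.0458), Osbpl3 in paraquat against TiO2 (0.0328) and Rarb, Myrf and Nrn1 in the mixture. Depth limits genes near the lowest mean of 5.53, where a floor of 3 reads is 1.98 to 3.25.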

Other observations

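The split counts below were planned beforehand except those that part the pairs, which were added after seeing the data, and the genes named here outside the naming rule were chosen after their values were seen. Genes of oxidative defence moved singly and not as a list (camera adjusted p = 0.918 in paraquat, 0.9 in TiO2 and 0.688 in the mixture). Gstm1, a glutathione transferase gene, rose in all 3 exposures (0.88, 0.63 and 0.72 on the log2 scale), glutathione reductase (Gsr) fell in paraquat (−0.34), and Gclc, of glutathione synthesis, fell in TiO2 (−0.33). The call of Gsr ended without paraquat 1 (adjusted p = 0.0896). That of Gstm1 ended in TiO2 without control 1 or 4 or TiO2 2 or 3 (up to 0.079) and in the mixture without any library except control 3 and mixture 4 (up to 0.115), in both with the GC correction (0.0839 and 0.0699, lowest over the alternatives 0.00659 and 0.0052) and in the mixture also with only the groups compared. The small heat shock gene Cryab rose in all 3 exposures (1.13, 0.72 and 0.69), from 280 ± 49.7 to 616 ± 121 in paraquat. Its call ended in TiO2 without library 3 of that group (0.0586) and in the mixture without any library except control 4 and mixture 4 (up to 0.132) and with voom or the GC correction (0.00167 to 0.0878 over the alternatives). The cochaperone gene Bag3 rose in paraquat and TiO2, from 36.7 ± 13.4 to 83 ± 23.9 and 75.6 ± 5.38. The heat shock list was not called (0.677, 0.6 and 0.166). Lists of dopamine handling and receptors (0.283, 0.901 and 0.592), genes of inherited parkinsonism (0.677, 0.779 and 0.11), inflammatory mediators (0.283, 0.815 and 0.44) and microglia (0.987, 0.42 and 0.592) were not called in any exposure.

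Other splits of the same libraries into groups of the same sizes were counted. For paraquat 1 of 35 splits, the real one, gave 1617 calls and the highest of the others 227. For TiO2 it was 1 of 35, with 996 and 400, and for the mixture 1 of 35, with 185 and 3. In each only the real split reached its count, which is the lowest share that 35 splits allow. These shares were not adjusted over the comparisons and take the libraries as independent, so chance is not excluded. For the interaction 1 of 100 splits drawn gave 1832 and the highest other 811. These splits moved all 15 libraries among the 4 groups, so they ask whether any groups differ. They cannot exclude chance for the interaction itself. For mixture against paraquat 4 of 35 splits gave at least its 1 call (highest other 8), so chance cannot be excluded for that count, in splits that ignore the library numbers. Of the 8 splits that part all 3 pairs only the real one had its 1 call, with or without the block (highest other 0), and in the block fit of the 2 groups the real one of 4 distinct splits had 107 and the highest other 13. So few splits give no share under 0.05, and they rest on pairs by number, whose correlation is not separate from shared sex-linked signal. Mixture against TiO2 (0 calls by limma, 1768 at an unadjusted p under 0.05, edgeR 0, voom 41, DESeq2 55) and paraquat against TiO2 (0 calls by limma, 997 at an unadjusted p under 0.05, edgeR 0, voom 11, DESeq2 15) have no calls to test: all 35 splits give at least 0, which says nothing about chance. The highest counts of their other splits were 1 and 108. A split with 108 calls where the real one has 0 points to a structure among these libraries, which was not identified or tested.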
